A study of Anas platyrhynchos with 5 samples.

How the data were processed

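Small RNA was sequenced from feather bulbs of ducks (Anas platyrhynchos) in 5 libraries. Per the series' design text, 3 bulbs from each duck were pooled, birds of the same breed were then combined into 1 library, and the Illumina reads were analysed with miRDeep2 2.1.2. Per the submitters' processing notes, FastQC and Bowtie 0.12.2 were also used. The genome build is not given in the sources used here. Per the labels the ducks were 12 months old. The number of birds in a pool is not stated, so p-values measure the spread between these libraries, which also differ in breed. No batch or sequencing date is given.

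Each deposited table lists hairpins with their mature miRNAs. The unit of the values used here is a raw read count per mature miRNA and per hairpin, as deposited by the authors. The authors also gave CPM (read counts scaled to a common total), which were checked and equal the raw count divided by the table's total to within 0.005. In every hairpin the deposited total count equals the mature reads plus the remaining reads. The tables hold 72 or 73 hairpins, and 134 distinct mature names were found over all of them. A mature miRNA listed under several hairpins was taken once, with its highest count. A hairpin not listed in the Kaiya table was taken as 0 in the tests and left out of ratios with that library. Blank or shifted sequence cells were found on 10 lines for Kaiya and 1 line for Cui Hei. Names and counts on these lines were used as given, and each sequence is the one most tables list. Names are those of the files. No duck miRNA annotation was used. Listed sequences were compared with human mature sequences written down from general knowledge.

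The depth, with each mature miRNA counted once, was 3476838 reads in the Cui Hei library, 1988317 in the black F2 library, 4269854 in the Kaiya library, 1601329 in the Liancheng library and 2843291 in the white F2 library. A count of 3 reads, taken as the floor, corresponds to between 0.729 and 1.86 CPM. Reads carry no molecular identifiers, so counting intervals and floors cover counting error only. All intervals are exact Clopper-Pearson intervals at the 95% level, or exact Poisson intervals for a single level.

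Black libraries (n = 2) were compared with white libraries (n = 3) by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter by colour and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05. The filter kept 114 miRNAs with 99.998% of the reads. The common dispersion was 0.0756, a biological coefficient of variation of 0.275. Standard errors (SE) were derived from the fitted change and its F statistic. Levels are TMM-normalised CPM as mean ± SD. In 50 simulated data sets per fold size with 20 of the 114 miRNAs changed, this black against white test recovered 26.5% of changes of 2-fold, 97.1% of 4-fold and 100% of 8-fold. Among 50 simulated sets without a change, 1 gave a call. The simulated counts followed the fitted dispersion trend, without extra spread of single miRNAs. They also held more changed miRNAs than the 2 called here, which eases the adjustment. Recovery is therefore likely lower in the real data, above all for miRNAs with a large SE, such as miR-2188-5p (0.82).

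Lists of miRNAs for pigmentation, cell types and families were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named miRNAs. Lists with at least 3 tested members were tested with camera (preset inter-gene correlation of 0.01, and an estimated correlation as an alternative) and with fry, both from limma 3.58.1. Comparisons of single libraries have no test. They are log2 ratios of TMM-normalised counts for miRNAs with at least 50 reads in the libraries compared, with the series' size criterion of a log2 ratio of at least 1 in either direction. Ratios of the 5p to the 3p arm, with a pseudocount of 0.5, were compared between colours with limma for hairpins with at least 50 reads on each arm. A test of whether the colour difference depends on stock (pure breed or F2) used edgeR with an interaction term and was added after the data were seen.

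Named in the text are the 10 miRNAs with the smallest p per direction, the 10 most abundant, and list members of at least 10 CPM that passed or whose colours did not overlap. For the F2 ratios the 10 highest and 10 lowest with at least 200 reads qualify, for the other ratios the 5 highest and 5 lowest, and for the arms the 5 with the smallest p. The text gives only some of these in full. Names of hairpins without a family number are not printed here.

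Alternatives were DESeq2 size factors, upper-quartile scaling, library size alone, other read filters, the DESeq2 1.42.0 Wald test, limma-voom, stock as a block, summed lines, and leaving out the most abundant miRNA, unlisted miRNAs or each library in turn. Hairpin totals, list membership by listed sequence (also with an estimated correlation and without miR-204), lists and ratios without miR-204, DESeq2 size factors for the comparison of F2 and pure-breed ratios, and arms without shared mature lines were added after the data were seen. Remaining reads outside the mature sequences entered the hairpin totals and are otherwise described only in the closing section, where a hairpin counts as cut if it ends with at least 15 bases, but not all, of a listed mature sequence. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.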

Results

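The series asks which miRNAs differ between black and white feather bulbs of ducks, the follicular base of the growing feather. It holds 5 small RNA libraries. The black group has 2 libraries, from the Cui Hei breed (black replicate 1) and from black birds of the F2 generation of a Kaiya-Liancheng cross (black replicate 2). The white group has 3 libraries, from the Kaiya breed (white replicate 1), the Liancheng breed (white replicate 2) and white birds of the same F2 generation (white replicate 3). Between 1601329 reads (Liancheng) and 4269854 reads (Kaiya) were assigned to mature miRNAs. In the pure breeds colour goes with breed, whereas both F2 libraries come from 1 cross.

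A few miRNAs made up most of every library. The 10 most abundant took between 68.9% of the reads in the black F2 library and 75.7% in the Kaiya library. The highest was miR-10b-1-5p, whose family is encoded in the HOX clusters, with a mean of 14.6% over the 5 libraries. It ranged from 13.6% (95% Clopper-Pearson interval 13.6% to 13.7%) in Liancheng to 17.5% (17.5% to 17.6%) in Kaiya. It was followed by let-7d-5p at a mean of 8.92%, the epithelial miR-205b-5p at 7.79%, miR-181b-1,2-5p at 7.13% and miR-22-3p at 6.59%. Next came miR-146b-1,2-5p at 6.56%, miR-26a-5p at 6.37%, miR-27b-3p at 5.05%, miR-10b-2-5p at 4.13% and miR-367-3p at 3.98%. The share of miR-10b-2-5p varied the most among these, from 1.58% in the black F2 library to 9.40% in Kaiya. None of the 10 passed the test between colours.

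Both arms of a single hairpin, mir-204, separated black from white bulbs. miR-204-5p, which shares its seed with the melanocyte-enriched miR-211, stood at 10240 ± 2058 CPM in black bulbs (SD, n = 2) and 110 ± 8.91 CPM in white bulbs (SD, n = 3). This is a 93.2-fold higher level in black, a log2 fold change of 6.54 ± 0.21 (SE), with an adjusted p of 1.2e-05 by edgeR. In the Cui Hei library miR-204-5p took 1.25% of the miRNA reads (95% Clopper-Pearson interval 1.24% to 1.27%) and in the black F2 library 0.917% (0.904% to 0.931%). In the white libraries its share was 0.00998% in Kaiya (0.00905% to 0.0110%), 0.0121% in Liancheng (0.0105% to 0.0139%) and 0.00978% in the white F2 library (0.00866% to 0.0110%). The other arm, miR-204-3p, stood at 27.9 ± 0.0119 CPM in black and 0.704 ± 0.0756 CPM in white bulbs, with a log2 fold change of 5.20 ± 0.28 (SE) and an adjusted p of 0.000124. It rests on 162 reads in the black and 6 reads in the white libraries, which give a ratio of 38.8 with a counting interval of 17.5 to 107. Its SDs are smaller than the counting error, with intervals of 22.8 to 33.8 CPM in Cui Hei and 0.0157 to 3.45 CPM in Liancheng. All 3 white libraries lay at or under the floor of 3 reads. Each arm was higher in both black libraries than in all 3 white ones.

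**Figure D1:**
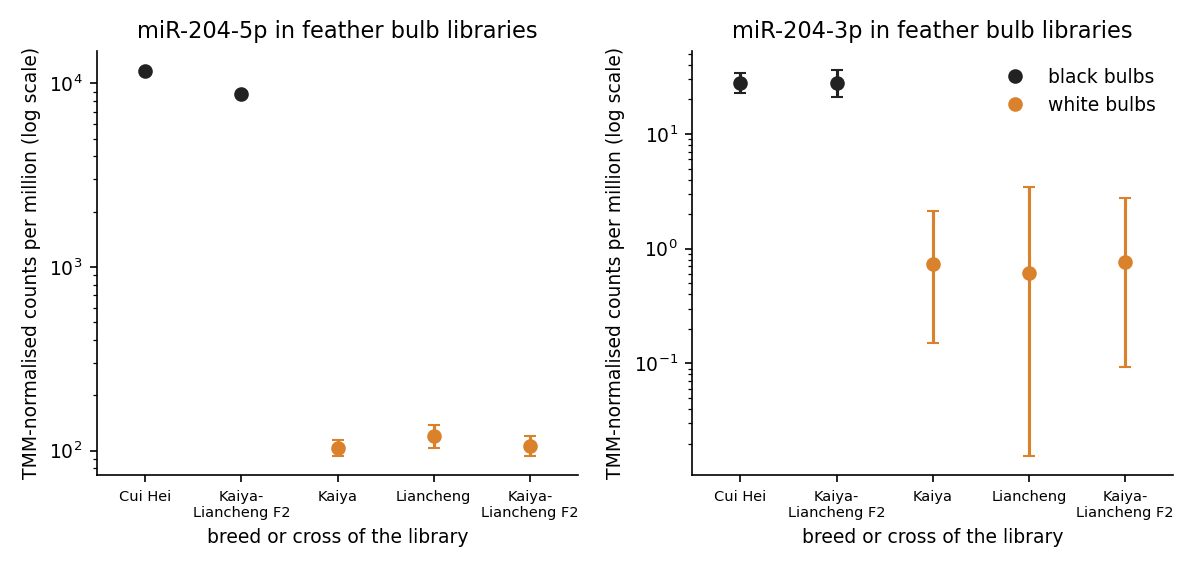
TMM-normalised CPM of miR-204-5p (left) and miR-204-3p (right) on log axes, with 1 point per library, black for black bulbs and orange for white bulbs. Bars are 95% exact Poisson intervals of the read count, and the 5p level is between 8785 and 11700 in the black libraries and between 104 and 120 in the white ones.

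No other miRNA passed the test. Of 114 tested, edgeR called 2 higher and 0 lower in black bulbs, and the DESeq2 and limma-voom tests called the same 2. At an unadjusted p under 0.05 there were 3 higher and 1 lower, the last being a 3p arm without a family number, listed as cugaaaaacugcagcacucccgga, at -0.95 ± 0.34 from 4 to 25 reads per library (-1.48 without Cui Hei, -0.65 without the black F2 library). The next in line on the higher side was miR-144-3p, an erythroid miRNA, at 324 ± 34.7 CPM in black and 136 ± 65.8 CPM in white bulbs, a log2 fold change of 1.24 ± 0.45. Its partner arm miR-144-5p had 0.79 ± 0.61, miR-130a-5p 0.79 ± 0.34, miR-2188-3p 1.03 ± 0.50 and miR-2188-5p 0.97 ± 0.82. Without the Liancheng library miR-144-5p had 0.38 and miR-2188-5p 0.48, and without Kaiya 1.19 and 1.77. Smaller positive values were those of miR-187-3p (0.43; 0.22 to 0.62 on leaving out a library), miR-15c-2-3p (0.35; -0.0017 without Cui Hei) and miR-128-3p (0.23; 0.13 to 0.42). On the lower side, miR-6564-3p had a log2 fold change of -0.91 ± 0.59, miR-449c-2-5p -0.48 ± 0.37, miR-30e-2-3p -0.38 ± 0.26, miR-449c-1-5p -0.37 ± 0.21 and miR-9-5p -0.34 ± 0.19. Single libraries weighed on these too: miR-449c-2-5p was -0.02 without Cui Hei and -1.06 without the black F2 library, miR-6564-3p -0.45 without Liancheng, miR-30e-2-3p -0.12 without the white F2 library and miR-9-5p -0.20 without Cui Hei. The adjusted p-values of all these were between 0.945 and 0.971. In 8 of the 114 miRNAs both black libraries lay above all white ones and in 9 below, 14.9% together, where chance gives 20%. Without white replicate 1 (Kaiya) edgeR also called miR-6564-3p lower (-1.34, adjusted p 0.0376), making 3 calls.

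**Figure D2:**
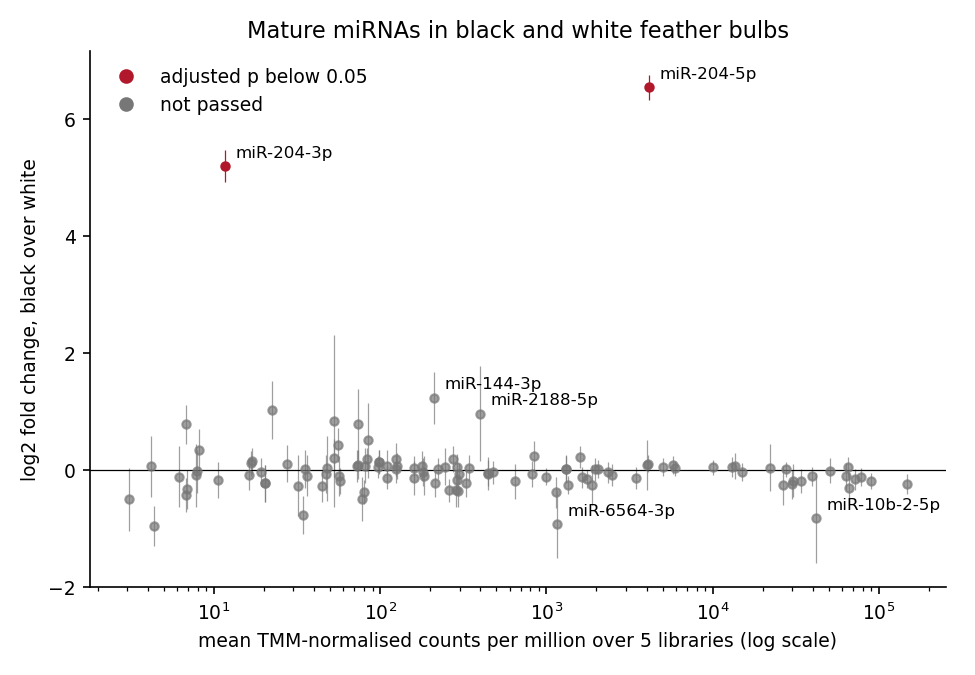
Log2 fold change of black over white bulbs against the mean TMM-normalised CPM (log axis) for the 114 tested miRNAs, with SE as bars. The arms of miR-204, at 6.54 and 5.20, are the only points past an adjusted p of 0.05.

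Of the pigmentation miRNAs, 2 of 14 tested members rose, 0 fell and 12 did not pass, and the count adjusted over the list alone was the same. The members that rose were miR-204-5p and miR-204-3p. The others lay near zero: miR-125b-5p had a log2 fold change of 0.09 ± 0.15, miR-148a-3p -0.24 ± 0.25, miR-222a-3p 0.11 ± 0.14 and miR-101-1,2-3p -0.04 ± 0.18. The camera test with preset correlation gave an adjusted p of 0.00406 for the list, and fry 0.0046. With an estimated correlation the camera call was lost (adjusted p = 0.234), as it was without the Liancheng library (0.401), without the black F2 library (0.0797) and without the miR-204 arms (0.975, in the other direction). The list's median was 0.04.

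The keratinocyte and epithelium list (miR-205, miR-200, miR-31 and related families) had 8 tested members, none of which passed, and an adjusted p of 0.885. Among them miR-205b-5p had a log2 fold change of -0.12 ± 0.15, miR-200a-3p -0.12 ± 0.18 and miR-31-5p -0.18 ± 0.21. The list's median was -0.14, and 7 members were negative with TMM scaling but 4 with library size alone. None of the 5 dermal mesenchyme members passed (median 0.06, adjusted p 0.975), with miR-22-3p at 0.06 ± 0.18 and miR-214-3p at 0.06 ± 0.22. The 5 neural members (median -0.18), the 5 HOX-encoded members (-0.23) and the 4 miR-30 members (-0.04) each had an adjusted p of 0.885, and the 8 members of the miR-17-92 families (0.11) one of 0.975. The lists with fewer than 3 tested members by name had no set test and no member that passed. They were the erythroid list (miR-144 arms, median 1.01), the leukocyte list (miR-146b arms, -0.22), the endothelial list (miR-126 arms, 0.05), the muscle list (miR-499 arms, -0.23) and let-7 (-0.05). The liver list, miR-122, had 0 tested members. Upper-quartile scaling moved the median of all miRNAs to -0.16 and turned the medians of the pigmentation, mesenchyme, endothelial and miR-17-92 lists negative, while library size alone moved it to 0.10 and turned let-7 and miR-30 positive.

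**Figure D3:**
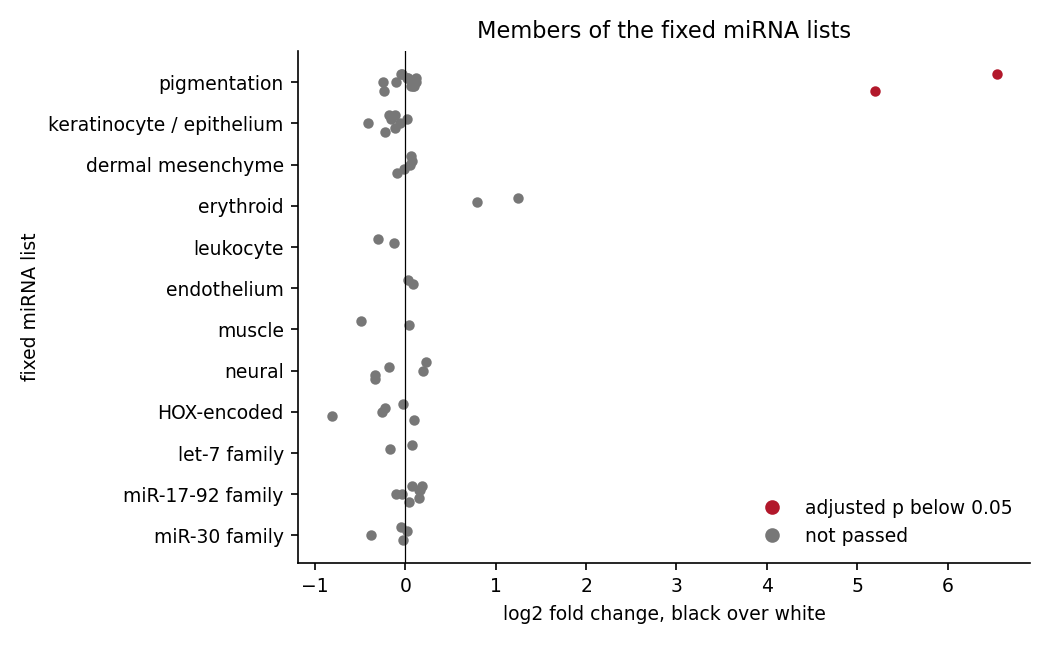
Log2 fold change of black over white bulbs for each tested member of the fixed miRNA lists, 1 point per mature miRNA and 1 line per list. The red points, the miR-204 arms in the pigmentation list, passed an adjusted p of 0.05, and the other members lie between -0.82 and 1.24.

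Within the F2 cross, black bulbs differed from white bulbs mainly in miR-204. miR-204-5p had a log2 ratio of 6.37 (counting interval 6.20 to 6.55), from 18237 reads in the black and 278 in the white library. Of 104 miRNAs with at least 50 reads, 3 reached a log2 ratio of 1 and 2 reached -1. The other high ones were miR-187-3p at 1.03 (0.65 to 1.42) and miR-204-3p at 5.19 (3.27 to 8.27), which was named after its value was seen. Of its 60 reads, 58 were in the black and 2 in the white library, the latter under the floor of 3 reads. The low ones were miR-10b-2-5p at -1.15 (-1.17 to -1.13) and miR-6564-3p at -1.02 (-1.10 to -0.94). Ratios between 0.82 and 0.95 were found for miR-144-3p, miR-2188-5p, miR-196-1,2,3-5p and miR-460a-5p, and miR-30e-2-3p (-0.85) and miR-125b-3p (-0.64) followed on the lower side. The interval excluded 0 for 72 miRNAs, but there is 1 library per colour, so the spread between birds is not covered. With library size alone 7 miRNAs reached 1 and 0 reached -1: miR-144-3p (1.13), miR-2188-5p (1.06), miR-196-1,2,3-5p (1.05) and miR-460a-5p (1.00) joined, while miR-10b-2-5p (-0.97) and miR-6564-3p (-0.84) dropped out.

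Among the pure breeds, the black Cui Hei library was again far above the white ones in miR-204-5p, at a log2 ratio of 6.82 to Kaiya, 6.60 to Liancheng and 6.71 to their mean. Against that mean, 7 of 109 miRNAs reached 1, and 1 reached -1. After miR-204, the highest were miR-2188-5p at 1.91, miR-144-3p at 1.67, miR-2188-3p at 1.64 and miR-144-5p at 1.49. Their size rested on Liancheng, and none of them reached 1 against Kaiya. The ratio of miR-2188-5p was 0.23 to Kaiya and 3.60 to Liancheng, and that of miR-144-5p 0.31 and 2.68. More remained against Kaiya for miR-144-3p (0.87, and 2.46 to Liancheng) and miR-2188-3p (0.73 and 2.55). On the lower side, a 5p arm without a family number, listed as uuccaguccauguaccaucagu, had -1.04, miR-449c-2-5p -0.90 and miR-6564-3p -0.57, the last at 0.47 to Kaiya and -1.62 to Liancheng.

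Kaiya and Liancheng are both white, so their ratio holds no difference in bulb colour, while breed, pool and library differ together. By SD and by the number of miRNAs reaching the size it was the most divergent of the 4 pairs of the same colour, but its median absolute log2 ratio of 0.295 was below that of Kaiya and white F2 (0.348) and of Liancheng and white F2 (0.357). The erythroid miR-144-3p was 1.59 higher (log2, Kaiya over Liancheng; counting interval 1.29 to 1.91), miR-144-5p 2.37 (1.81 to 2.99) and miR-2188-5p 3.37 (3.06 to 3.70). The abundant miR-10b-2-5p had a ratio of 2.26 (2.24 to 2.28) and miR-10b-2-3p 1.68. Higher in Liancheng were miR-460a-5p at -2.31 (-2.67 to -1.95), miR-6564-3p at -2.09 (-2.17 to -2.01), miR-21-5p at -1.16, miR-6595-3p at -1.15 and miR-21-3p at -1.00. In all, 7 of 103 miRNAs reached 1 and 6 reached -1, 13 together. Over 110 miRNAs common to all pairs, with the miR-204 arms left out, 4 to 15 reached the size in the 4 pairs of libraries of the same colour (4, 7, 12 and, for Kaiya and Liancheng, 15) and 4 to 10 in the 6 pairs of different colour. Over the same miRNAs the SD of the log2 ratio was 0.383 to 0.777 in the same-colour pairs (mean 0.590) and 0.425 to 0.693 in the different-colour pairs (mean 0.550).

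**Figure D4:**
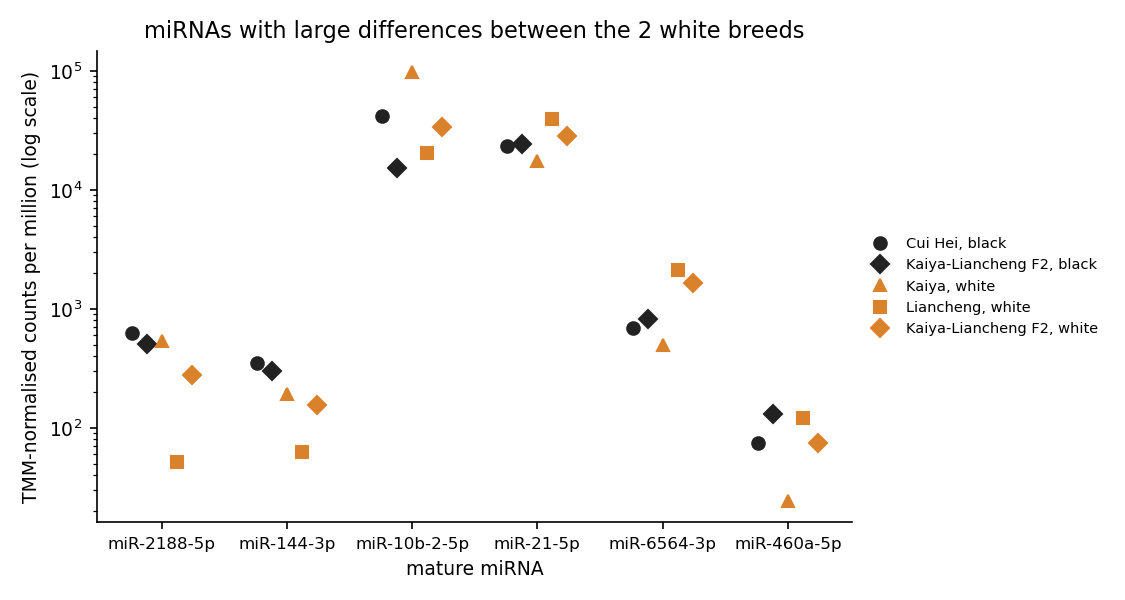
TMM-normalised CPM (log axis) of 6 miRNAs with large ratios between the Kaiya and Liancheng libraries, 1 point per library, with the shape showing the breed or cross and black or orange the bulb colour. miR-2188-5p lies at 52.0 in Liancheng and between 277 and 630 in the other libraries.

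The F2 and pure-breed colour ratios, which share no library, agreed mainly in miR-204. Across 103 miRNAs, which are not independent replicates, Pearson's r was 0.880 and Spearman's rho 0.203, and 61 (59.2%) had the same sign. Without the Kaiya library rho was 0.0741. Both ratios reached 1 in the same direction for 2 miRNAs, the arms of miR-204. Without these arms r was 0.381 and rho 0.155, and 0 of 101 miRNAs reached the size in both. The edgeR test of whether the colour difference depended on stock had 1 residual degree of freedom. This is the difference between Kaiya and Liancheng, since the other groups had 1 library each. The test therefore cannot decide the question. The F2 colour difference minus the pure-breed one was -0.34 (log2) for miR-204-5p and -0.13 for miR-204-3p.

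**Figure D5:**
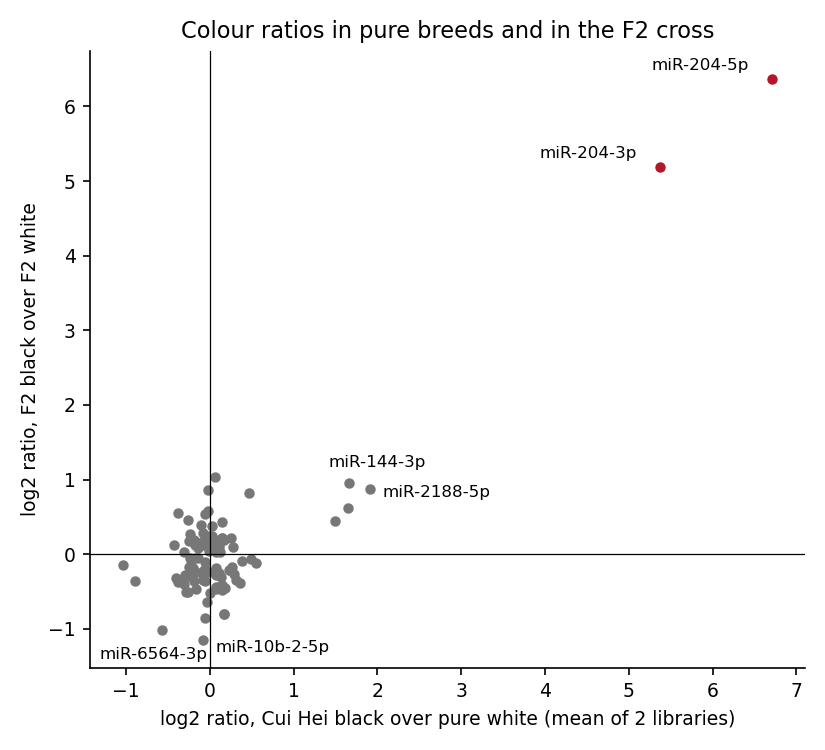
Log2 ratio of F2 black over F2 white bulbs against the log2 ratio of Cui Hei over the mean of the pure white libraries, 1 point per miRNA with at least 50 reads in each comparison. The miR-204 arms lie alone at the upper right, with miR-204-5p at 6.71 and 6.37.

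In the balance of the arms, limma called 1 of 48 hairpins, mir-204, but its white side rests on 6 reads of the 3p arm, with 1 to 3 per library. Its log2 ratio of 5p to 3p reads was 8.49 ± 0.30 in black (SD, n = 2) and 6.92 ± 0.11 in white bulbs (SD, n = 3), a difference of 1.58 ± 0.24 (SE) with an adjusted p of 0.0161 by limma. The next hairpin, mir-130a, had a difference of 0.84 ± 0.32 (adjusted p 0.709), mir-429 one of -0.50 and mir-10b-2 one of -0.58. Without Cui Hei the last pair were -0.79 and -1.07, and without the black F2 library -0.21 and -0.10. At an unadjusted p under 0.05 there were 3 hairpins, these first 2 (mir-204 and mir-130a) and 1 without a family number. The spread of the white mir-204 ratios covers less than their counting error, and the pseudocount bears on them. With reads pooled by colour, the 3p share of miR-204 reads was 0.664% in white (interval 0.244% to 1.44%) and 0.261% in black (0.223% to 0.305%). The intervals overlap, the white one barely holding the black share. Overlap is not a test, and the pooled shares were not compared directly. The call was lost without Cui Hei (difference 1.37, adjusted p 0.188), without Kaiya (1.58, 0.127) and without the white F2 library (1.52, 0.0834), where the difference stayed similar and fewer libraries were compared. With at least 200 reads required on each arm mir-204 was not tested.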

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

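The test of this part was chosen after the reads had been seen. Reads that fell on a hairpin but outside its listed mature sequences, which the comparisons of mature miRNAs did not use and which entered only the alternative on hairpin totals, were concentrated in 1 place: mir-27b-1 held 344461 of them over the 5 libraries, 99.3% of all 346849 such reads. They drew attention because they are a signal outside the main measurement. The listed mir-27b-1 hairpin has 62 bases and is mir-27b-2, of 63 bases, without its last base, so it holds 20 of the 21 bases of miR-27b-3p. A likely source is therefore miR-27b-3p itself, since the shorter hairpin has only a 5p sequence listed and no 3p sequence to take such reads. The next hairpin, mir-146b-1 with 1333 remaining reads, and mir-18a-1 with 233 are also cut 1 base short of a 3p sequence, whose own counts were 1537 for miR-146b-2-3p and 245 for miR-18a-2-3p. Among hairpins that hold their mature sequences whole, the highest share of the remaining reads was 0.108%, at mir-146b-2. The hairpins mir-106-2 and mir-455-1 also end short of a 3p sequence listed for their copy, but had 0 remaining reads. Each of them has another 3p sequence listed (miR-106-2,3-3p and miR-455-1,2-3p). By contrast, mir-27b-1, mir-146b-1 and mir-18a-1 have only a 5p sequence listed. The ratio of the mir-27b-1 remaining reads to miR-27b-3p reads lay between 0.415 (Kaiya) and 0.555 (white F2) and was not ordered by colour. No biological explanation was tested.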

How the results depend on the processing

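The same 2 miR-204 arms were called higher in black bulbs under all alternatives that count mature miRNAs, and the log2 fold change of miR-204-5p ranged from 6.34 to 6.74. Hairpin totals, chosen after seeing the data, gave 1 call, mir-204, since both arms are then 1 feature. Leaving out a library gave 2 to 3 calls. The count of lists with a call, 1, fell to 0 with an estimated correlation and to 0 without the miR-204 arms (chosen after seeing the data, as were lists by sequence, which gave the same 0 under both), where the pigmentation list had an adjusted p of 0.975 and turned to the lower side (0.948 with lists by sequence) because its 2 called members were gone; leaving out a library gave 0 to 1. Lists without a call also turned direction: dermal mesenchyme with stock as a block (adjusted p 0.819) and without Liancheng or the black F2 library (0.401 to 0.927 over the left-out libraries), HOX-encoded without Kaiya (0.401 to 0.880) and miR-17-92 without Cui Hei or the white F2 library (0.470 to 0.880), where the cause was not tested. Requiring 10 reads raised the F2 count from 5 to 8, since rarer miRNAs enter. The arm count fell to 0 with 200 reads per arm, which removes mir-204, and was 0 to 1 on leaving out a library. Summing the lines of a mature miRNA raised the mean share of each library's own 10 most abundant miRNAs from 72.1% to 75.2%. The pure-breed count was 6 to 9 and Spearman's rho between F2 and pure-breed ratios 0.0741 to 0.257 on leaving out a library. The log2 fold change of miR-15c-2-3p ranged from -0.0017 to 0.589 on leaving out a library; the cause was not tested. Apart from the left-out libraries, 32 main values and 350 single values recomputed under alternatives kept their side of the test or, where there was no test, stayed near the main value (counts within 1.5 times, ratios within their interval or spread). Another 25 single values moved past their counting interval, all of them ratios of single libraries under other scalings. Ratios near the size of 1 could cross it without such a move, as F2 miR-6564-3p (-0.98) and Kaiya over Liancheng miR-21-3p (-0.91) did with DESeq2 size factors and F2 miR-144-3p (1.13) and miR-460a-5p (1.00) with library size alone, where the F2 count was 7, all higher, in place of 3 higher and 2 lower. Depth limits the 3p arm of miR-204 in white bulbs, with 1 to 3 reads per library.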

Other observations

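List membership by sequence and the tests of scaling, of another hairpin, of carry-over, of the hairpin's identity and of red blood cells were chosen after the values were seen. The tests of depth and of other splits of the libraries were written beforehand. The low miR-144 and miR-2188 in Liancheng that the depth test concerns were nevertheless picked from the values.

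Several names in the files differ from the family that the listed sequence matches. The sequence of miR-6564-3p is that of human miR-184 in 22 of 22 bases, an epithelial miRNA, and it had a log2 fold change of -0.91 ± 0.59 between colours. That of miR-6595-3p equals miR-143-3p in 21 of 21 bases, a mesenchymal miRNA, at 22551 ± 3517 CPM in black and 21838 ± 9233 CPM in white bulbs. The abundant miR-367-3p equals miR-92a-3p in 22 of 22 bases, miR-181b-1,2-5p equals miR-181a-5p in 23 of 23, let-7d-5p equals let-7f-5p in 22 of 22 and miR-10b-2-5p matches miR-10a-5p in 22 of 22. The sequence of miR-449c-2-5p, at -0.48 ± 0.37 between colours, equals miR-34a-5p in 22 of 22 bases. With lists filled by listed sequence, the pigmentation list had an adjusted p of 0.00663 by camera. The keratinocyte list had 0.793 and now 10 members. It gained miR-184 and a 3p arm without a family number, which matches miR-203a-3p at 20 of 21 bases and had -0.18 ± 0.28. The mesenchyme list, also of 10 members, had 0.948. It now held arms matching miR-199a-5p (23 of 23 bases, 0.01 ± 0.19) and miR-199a-3p (21 of 21, 0.06 ± 0.17). As with the list by name, the pigmentation call was lost with an estimated correlation (adjusted p = 0.286) and without the miR-204 arms (0.948). The leukocyte list held 4 members by sequence, with arms matching miR-142-5p (21 of 21 bases, 0.24 ± 0.26) and miR-142-3p (23 of 23, 0.10 ± 0.25). Its median was -0.01 and its adjusted p 0.948 by camera, against a median of -0.22 for the miR-146b arms alone.

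The higher miR-204 level of black bulbs was weighed against technical sources. Scaling between libraries is argued against by the log2 fold changes of miR-204-5p under other scalings. They were 6.41 (upper quartile), 6.54 (DESeq2 size factors) and 6.68 (library size alone). The lowest value over all alternatives, 6.34, was that without Cui Hei. Reads of another hairpin with the same 5p sequence cannot be the whole source, since the log2 fold change of miR-204-3p minus 2 SE was 4.64, and the wider counting interval of its ratio, which covers the few white reads, still began at 17.5. In 1 of the 10 ways to split the 5 libraries into 2 and 3, the real one, 2 miRNAs were called, and the highest of the others called 0, but 10 splits are too few for a share under 0.05. Every other split also mixes black and white libraries in a group, so the miR-204 difference becomes spread there and could hardly be called. At an unadjusted p under 0.05 by edgeR the real split had 4 miRNAs, and the others had 0 to 13. In the pure breeds colour goes with breed, which stays open there, and a melanocyte content that differs between black and white bulbs was not tested.

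The 898 miR-204-5p reads of the white libraries are 1.43% of all its reads. They could be carried over from the black libraries: the 3p share was 0.664% in white bulbs, whose interval of 0.244% to 1.44% holds the 0.261% of black bulbs, and 6 reads are too few to tell carry-over from low expression. The hairpin itself may be the duck counterpart of miR-211, whose human gene lies in an intron of the melanocyte gene TRPM1. Its listed 3p sequence gcagggacagcaaagggaugcuc matches human miR-211-3p at 20 of 21 bases and human miR-204-3p at 16, while its 5p sequence matches miR-204-5p at 22 of 22 and miR-211-5p at 20. No duck genome was searched, so its position is not settled.

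The Liancheng library was low in miR-144 and miR-2188. A depth difference shared by all miRNAs is removed by the scaling, which also centres most of them. The test of depth could thus only show a loss limited to miRNAs of similar abundance. None was seen: over 44 of these the median log2 ratio to the other libraries was 0.1 (quartiles -0.108 and 0.413). A smaller share of red blood cells in that pool could be a source: miR-144 is the only erythroid family measured, while miR-2188 was in no list fixed beforehand. All 4 arms were lower there than in the lowest other library, by log2 ratios of -1.30 for miR-144-3p (counting interval -1.62 to -0.98), -2.02 for miR-144-5p (-2.66 to -1.43), -1.82 for miR-2188-3p (-3.0 to -0.83) and -2.41 for miR-2188-5p (-2.76 to -2.08). A common factor within these intervals was predicted and fails for the pair of miR-144-3p and miR-2188-5p, but the intervals leave out the spread between pools, so the source stays open. Breed and pool cannot be told apart here, with 1 library each.

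The counts of miR-138-1-3p and miR-449c-1-3p were identical in all 5 libraries, at 3, 4, 11, 5 and 2 reads in Cui Hei, black F2, Kaiya, Liancheng and white F2, although their listed sequences differ. The overlapping miR-455-1,2-3p and miR-455-2-3p also had identical counts (79, 32, 66, 36 and 70 reads in the same order). The counts of miR-106-2,3-3p and miR-106-3-3p differed only in Liancheng (172 and 171 reads). Both members of these last pairs were tested separately. In the arm comparison mir-106-2 and mir-106-3 had the same values, as did mir-455-1 and mir-455-2.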
